A study of Fusarium oxysporum with 6 samples.

How the data were processed

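RNA was extracted from mycelium collected after 72 hours of culture, and libraries were made with an Illumina kit for total RNA, per the labels' protocols. The 6 libraries fell into 2 groups by their treatment label, 3 control and 3 with 80 µg/mL of thymol. Bowtie 0.12.2 is named in the submitters' processing notes. The counting tool, the genome build, the annotation and the authors' statistical test are not given in the sources used here.

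The authors deposited FPKM values (fragments scaled to gene length and to the mapped total of a library) per gene and library. That unit is not named in the file, and it was taken from the form of the values. The header of that table names its columns 1 place to the left of the values, and columns were matched by sample name. FPKM divides by a total for each library, so a few abundant genes that change can move all others. The authors deposited also a table of genes they had called, with a log2 fold change, a false discovery rate (a p-value adjusted for multiple tests), a value per group on a count-like scale that is named in no source used here, and annotations. That table holds 4869 genes. Gene identifiers (19832 FOXG locus tags and 1424 XLOC loci) were used as the files give them. None of them (0 matched) was found among the identifiers of the 16502 genes of the reference gene table, which is of assembly ASM1308505v1, so no coordinates are given. Product names are best hits, taken from Swiss-Prot, else the nr database, else Pfam, else KOG, as the authors' deposited table lists them, and they do not establish function.

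FPKM values are not counts, so the count model planned for a table of counts was not used, and the test planned for FPKM was. Genes with a mean of at least 1 FPKM in either group were kept (8478 genes) and log2(FPKM + 1) was fitted with limma 3.58.1 (with a mean-variance trend) in R 4.3.3, thymol minus control, with no covariate. The adjusted p is Benjamini-Hochberg, with a threshold of 0.05. A gene below 1 FPKM in either group passes the filter only if it stands higher in the other group, which favours calls in that direction among low genes. The share of calls that were higher under thymol was 76.5% with this filter. It was 73.5% with no filter and 78.9% with at least 1 FPKM in all 6 libraries. Each library's relative depth was read from the most common ratio of low values between it and control replicate 1. No 2 libraries were identical. Exact zeros were kept as values in the fits. In 48 genes a single control library stood at 0 beside 2 others at 10 FPKM or more, and in 54 genes a single thymol library did.

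Of the 29 gene lists, a gene belonged to a list when its product name matched a pattern fixed before the data were examined. Lists with at least 5 tested members (24 lists) were compared by a two-sided Fisher's exact test of membership against direction among annotated called genes, with Benjamini-Hochberg adjustment over the lists. Camera (preset correlation 0.01, and an estimated correlation) and fry, both of limma, were run over the annotated tested genes as alternatives. Fry tests whether a list's genes move, on balance, in 1 direction, and does not compare them with other genes. Named genes followed a rule fixed before the data were examined. It took the 8 largest rises and the 8 largest falls among genes past the threshold whose 3 thymol libraries lay all above or all below the 3 control libraries, with a named product and a mean of at least 10 FPKM in the higher group. Names containing words such as predicted or uncharacterized were left out. For each list it took the 2 called members with the largest change and the most abundant member, with 1 name per product, up to 30 genes in all, lists with the lowest adjusted p first. MCM1, CGR1 and FOXG_12240 were named outside this rule, after their values were seen.

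Alternatives were other scalings, a pseudocount of 0.1, no filter, a filter of at least 1 FPKM in all 6 libraries, a test against a fold of 1.5, and leaving out each library in turn. Group sums, lists and permutations were computed with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures with Matplotlib 3.10.9. The limma fit was tested on data simulated 5 times for the 8478 genes, with 200 genes at 10 FPKM or more changed by known sizes. It called 48.4% of changes of log2 1, 68.0% of 1.5, 81.2% of 2 and 88.0% of 3, and 8.3% of all calls were false on average, above the nominal 5.0%. Far fewer genes changed in the simulation than were called in the data, and the adjusted threshold depends on that number. These shares therefore need not hold for the data. The list test was tried on 200 shuffles of the directions of the 2512 called annotated genes, and called any list in 5.0% of them. Shuffling removes any correlation between the members of a list, so that share holds only for independent genes. When 95% of the members of a list of 20 or more were set to rise, it called 5 of 8 such lists.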

Results

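Gene expression was measured by RNA sequencing in Fusarium oxysporum f. sp. niveum, the fungus that causes wilt of watermelon. Cultures were grown in potato dextrose broth, with shaking at 150 rpm and 28 °C for 72 hours. The control group had 3 libraries from cultures without thymol, and the thymol group had 3 libraries from cultures with 80 µg/mL of thymol, a phenolic monoterpene of thyme oil. The series describes the replicates as biological. The deposited table gave FPKM values for 21256 genes, of which 6753 were listed at 0 in every library. Between 6776 and 6924 genes reached 1 FPKM in the control libraries, and between 7486 and 7684 did in the thymol libraries. The absolute depth is unknown. The steps between low values gave depths relative to control replicate 1 of 1.21 and 1.05 for control replicates 2 and 3, and of 1.12, 0.929 and 1.01 for the thymol libraries, so the groups overlapped. Correlations of log2(FPKM + 1) across genes, which are not independent replicates, were 0.90 to 0.93 between libraries of a group and 0.74 to 0.77 between groups.

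The comparison asked which genes changed when the fungus grew with thymol. The largest rises included ABC transporters, genes with best hits to cell surface proteins and a gene with a best hit to sec31, and the largest falls a pigment polyketide synthase, a nitrilase, a metallothionein and the surface adhesin FLO11. The ABC transporter FOXG_13653 (best hit CDR4 of Candida albicans, a family that includes drug exporters) went from 1.72 ± 0.241 FPKM in control to 549 ± 77.7 FPKM under thymol (SD, n = 3 each). The polyketide synthase FOXG_04757 (best hit a synthase of conidial yellow pigment) went from 961 ± 78.9 to 2.60 ± 0.378 FPKM. Of 8478 genes tested with limma, 4810 changed (Benjamini-Hochberg adjusted p under 0.05) on the values as deposited, 3682 of them higher and 1128 lower under thymol.

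The median tested gene was 0.60 higher on the log2 scale under thymol. The log2 changes of single genes below are given relative to that median, with the adjusted p of the limma fit in which the median gene was set to 0. That fit took 0.60 off every log2(FPKM + 1) value of the thymol libraries and did not rescale FPKM. A gene near 0 FPKM was thus lowered as much as an abundant one, which overstates falls and understates rises of low genes. FPKM values are as deposited. All changes are on the log2(FPKM + 1) scale, which by itself understates the change of genes at low FPKM.

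Among the 8 largest rises, FOXG_13653 rose by 7.05 ± 0.148 (SE, adjusted p = 1.99e-05). A second ABC transporter, FOXG_03541 (best hit SNQ2 of budding yeast, a multidrug exporter), rose by 5.76 ± 0.147, from 7.08 ± 1.11 to 660 ± 63.4 FPKM. Not all ABC transporters rose: FOXG_02985 (best hit CGR1 of Candida glabrata) fell by 3.84 ± 0.198 (log2 -3.24 as deposited), from 11.5 ± 2.47 to 0.313 ± 0.145 FPKM. The list of ABC transporters had 3 members higher and 2 lower (Fisher's exact test, adjusted p = 1.0). It was matched by product name and so did not include FOXG_03541. Of 17 called annotated genes with the Pfam domain ABC transporter, 12 were higher and 5 lower, and 8 and 5 relative to the median gene. The highest level under thymol among these genes was that of FOXG_19094 (best hit sec31, a vesicle coat protein, though no Pfam domain was listed), which went from 17.1 ± 3.94 to 2771 ± 200.1 FPKM. No Pfam domain was listed either for FOXG_10488 and FOXG_11567, which are named by best hit alone. FOXG_10488 (best hit a chitinase-like protein) rose by 6.05 ± 0.241 and FOXG_04522 (cryparin, a hydrophobin that coats aerial structures) by 6.05 ± 0.233. FOXG_03558 (adhesin EAP1, with a CFEM domain) went from 1.35 ± 0.249 to 211 ± 61.4 FPKM. FOXG_11567 (best hit the anchorage subunit of a-agglutinin, a mating adhesin) went from 23.1 ± 5.76 to 1712 ± 470 FPKM. FOXG_01269 (conidiation-specific protein 10, expressed during spore formation in Neurospora) went from 0.355 ± 0.044 to 96.4 ± 3.41 FPKM. The adjusted p of these 8 genes ran from 1.99e-05 to 1.03e-04.

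Among the 8 largest falls, FOXG_04757 fell by 8.67 ± 0.129 (SE). FOXG_13434, a nitrilase, went from 744 ± 181 to 1.89 ± 0.941 FPKM and FOXG_03480, a metallothionein that binds metal ions, from 202 ± 24.2 to 1.76 ± 0.470 FPKM. FOXG_05094 (a glyoxalase-like domain) fell by 6.70 ± 0.405, from 580 ± 106 to 8.26 ± 4.92 FPKM. FOXG_17184 (an FAD binding domain) fell by 6.63 ± 0.252, from 98.9 ± 12.3 to 0.573 ± 0.507 FPKM. The adjusted p of these genes and the next 3 lay between 1.11e-05 and 1.60e-04.

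The other 3 genes were listed at 0 in every thymol library, which is not a measure of absence, since the authors' deposited table gave other genes listed at 0 a sizeable value. FOXG_04758 (same best hit as FOXG_04757, with a thioesterase domain) stood at 1907, 1516 and 3061 FPKM in the control libraries, and the authors' deposited table gave it a log2 fold change of -9.38. The thioesterase domain is not among those listed for FOXG_04757, which include the synthase and acyl transferase domains. Whether these 2 consecutive locus tags are separate genes was not tested, and they are counted as 2 genes throughout. FOXG_02983 (best hit the flocculation protein FLO11, a cell surface adhesin) stood at 228, 322 and 146 FPKM in control, with -4.56 in the authors' deposited table. FOXG_11647 (cipB, an alcohol dehydrogenase domain) stood at 53.3, 60.5 and 65.5 FPKM in control. The authors' deposited table gave that gene group values of 4412 in control and 1375 under thymol, and a log2 fold change of only -1.68.

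**Figure D1:**
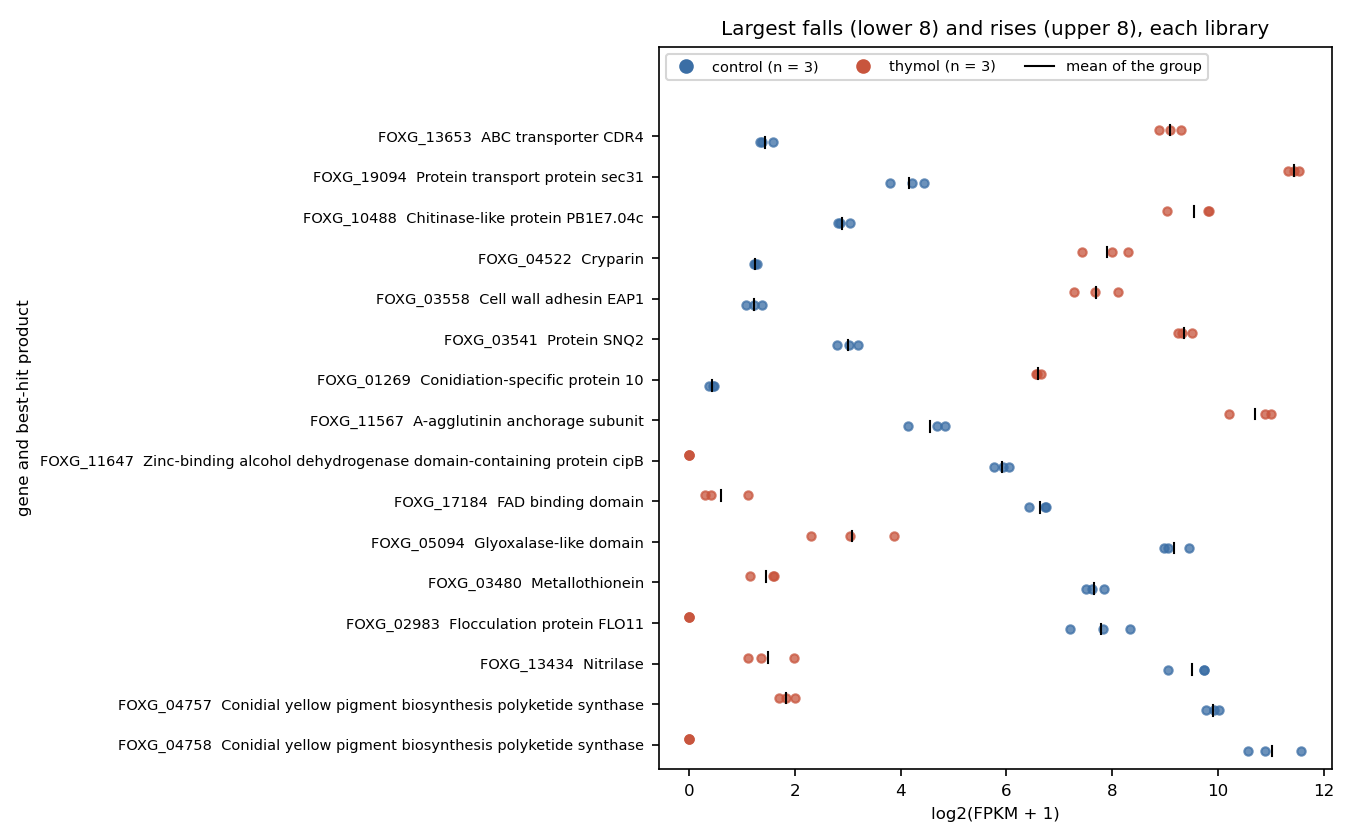
The horizontal axis is log2(FPKM + 1) and each row is a gene with its best-hit product. Points are single libraries of the control (blue, n = 3) and thymol (red, n = 3) groups, and ticks are means of the log2 values, left out where a group is listed at 0. For FOXG_13653 the thymol libraries lie far above the control libraries (549 against 1.72 FPKM), and for FOXG_04757 far below (2.60 against 961 FPKM).

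The excess of genes called higher depended on the scaling. With an absolute log2 change of at least 1, 2427 genes were called higher and 732 lower on the values as deposited, and 1031 and 1396 relative to the median gene. With that limit median-ratio scaling gave 1427 higher and 1097 lower, upper-quartile scaling 1257 and 1215, and quantile normalization 1161 and 1232. The following counts have no limit on the change. Relative to the median gene, 1784 genes were called higher and 2048 lower. Median-ratio scaling gave 2521 higher and 1716 lower, upper-quartile scaling 2255 and 1903, quantile normalization 2103 and 1882, and an equal FPKM sum in each library 3289 and 1276. An equal FPKM sum that left out the 100 most abundant genes of either group gave 2659 higher and 1582 lower. The most abundant 100 genes held 44.2% to 45.7% of the FPKM sum in control libraries and 33.8% to 35.5% in thymol libraries.

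**Figure D2:**
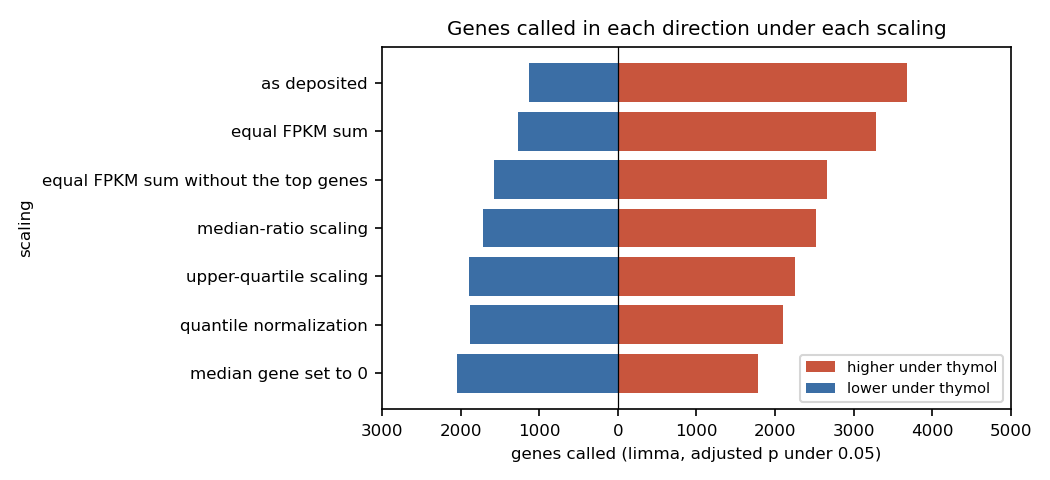
Bars are the numbers of genes called by limma (adjusted p under 0.05), higher under thymol to the right of 0 and lower to the left, for each scaling of the FPKM values. The excess of higher calls (3682 against 1128 as deposited) turns into an excess of lower calls when the median gene is set to 0 (1784 against 2048).

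Among 29 gene lists fixed before the data were examined, the list of DNA replication and cell division had 39 of 47 tested members higher under thymol, 2 lower and 6 not called. It was the list that passed Fisher's exact test on the values as deposited (adjusted p = 4.28e-05), but against all other annotated genes it had camera adjusted p = 0.631 with an estimated correlation. FOXG_08459 (PSF2 of the GINS complex, part of the replicative helicase) went from 0.197 ± 0.141 to 5.67 ± 0.758 FPKM (SD, n = 3 each), a rise of 1.88 ± 0.167 relative to the median gene (limma adjusted p = 4.93e-04). FOXG_06205 (the helicase-nuclease dna2) went from 0.173 ± 0.110 to 5.11 ± 0.396 FPKM, a rise of 1.78 ± 0.146. The most abundant member, FOXG_00572, went from 323 ± 11.2 to 176 ± 74.8 FPKM. Its best hit is SLD5, a GINS subunit, but its listed Pfam domains are those of a short chain dehydrogenase and not of GINS. It fell by 1.55 ± 0.285 relative to the median gene (limma adjusted p = 0.00691). Its fall on the values as deposited (log2 -0.95, limma adjusted p = 0.0323) lost its call without any of the control replicates, or without thymol replicate 2 or 3, at adjusted p of 0.0741 to 0.0935.

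The lists could be tested only within 3254 tested genes that carried an annotation, which is given for the genes the authors had called. Within them 2512 genes were called here, 1566 higher and 946 lower. Because the authors chose this pool on the same libraries, a list's direction is not independent evidence, and members that the authors did not call were not seen. The 2-sided Fisher's exact test compared list membership with direction over 24 lists. For DNA replication and cell division camera gave adjusted p = 9.88e-04 with a preset correlation of 0.01, and adjusted p = 0.631 with an estimated correlation. Relative to the median gene 30 members were called higher, 3 lower and 14 not called (Fisher's exact test, adjusted p = 1.38e-05). The 41 calls were 41 also when adjusted over the list alone. The list held 10 reverse transcriptases, enzymes of mobile elements, of which 9 were higher and 1 lower. It also held MCM1, a transcription factor, at FOXG_03102, which went from 10.5 ± 5.04 to 52.3 ± 8.51 FPKM. Without the reverse transcriptases, 30 of 37 members were higher and 1 lower (Fisher's exact test, adjusted p = 3.48e-04).

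Cell wall genes were mostly higher: of 35 tested members of the list of cell wall synthesis and remodelling, 25 were higher, 4 lower and 6 not called. The most abundant was FOXG_18811 (the glucanosyltransferase gel4, which joins beta-1,3-glucan chains in the wall), which rose by 1.89 ± 0.143 relative to the median gene, from 463 ± 36.7 to 2625 ± 332 FPKM. FOXG_10488 had the largest rise, and FOXG_16838 (endochitinase A) the largest fall, from 206 ± 34.8 to 3.59 ± 1.08 FPKM (log2 -6.12). The list did not pass on the values as deposited (Fisher's exact test, adjusted p = 0.0638) and passed relative to the median gene, with 23 higher and 6 lower (adjusted p = 0.0152). It had camera adjusted p = 0.0691 and adjusted p = 0.631 with an estimated correlation.

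In the list of secondary metabolism 8 of 11 tested members were lower, 2 higher and 1 not called (Fisher's exact test, adjusted p = 0.0638, and 0.326 relative to the median gene). Without the filter the adjusted p was 0.351. Over all 29 annotated members the authors' deposited table had 12 higher and 17 lower (adjusted p = 0.654), against 2381 and 2488 of all its genes. FOXG_04758 and FOXG_04757 are members. FOXG_09569 (best hit an O-methyltransferase of sterigmatocystin synthesis) went the other way, from 0.099 ± 0.068 to 18.8 ± 2.65 FPKM. Of 28 MFS transporters, membrane carriers of sugars, drugs and other solutes, 12 were lower, 6 higher and 10 not called (adjusted p = 0.0843). Relative to the median gene 18 were lower and 5 higher (Fisher's exact test, adjusted p = 0.0824). The MFS list passed in 8 of 20 alternatives, among them no filter (adjusted p = 0.00875), median-ratio scaling (0.0397), upper-quartile scaling (0.0352) and any annotation column (0.00451), and had adjusted p = 0.631 with an estimated correlation. FOXG_13342 (named for the family alone) fell by 3.46 ± 0.212 (log2 -2.86 as deposited) and FOXG_15291 (the sugar transporter STL1, a glycerol carrier in yeast) rose by 2.22 ± 0.155. The most abundant member, FOXG_12240 (named for the family alone), fell from 805 ± 130.0 to 221 ± 73.2 FPKM. FOXG_08237 (best hit the sulfite pump SSU1), which the words efflux pump put in the list although it has no MFS domain listed, stood at 18.3 ± 5.47 FPKM in control and 14.4 ± 2.35 under thymol (limma adjusted p = 0.349 as deposited, and 0.0306 relative to the median gene). Of 32 proteasome and ubiquitin genes, 21 were higher and 4 lower (Fisher's exact test, adjusted p = 0.112), and relative to the median gene 18 and 7. FOXG_00189 (proteasome subunit beta type-7) went from 14.3 ± 2.42 to 63.2 ± 4.25 FPKM and FOXG_08380 (the ubiquitin-activating enzyme E1) from 16.6 ± 5.21 to 67.9 ± 3.77 FPKM. FOXG_05141 (best hit the autophagy enzyme atg7) stood at 521 ± 159 and 248 ± 147 FPKM, which did not pass (limma adjusted p = 0.129).

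**Figure D3:**
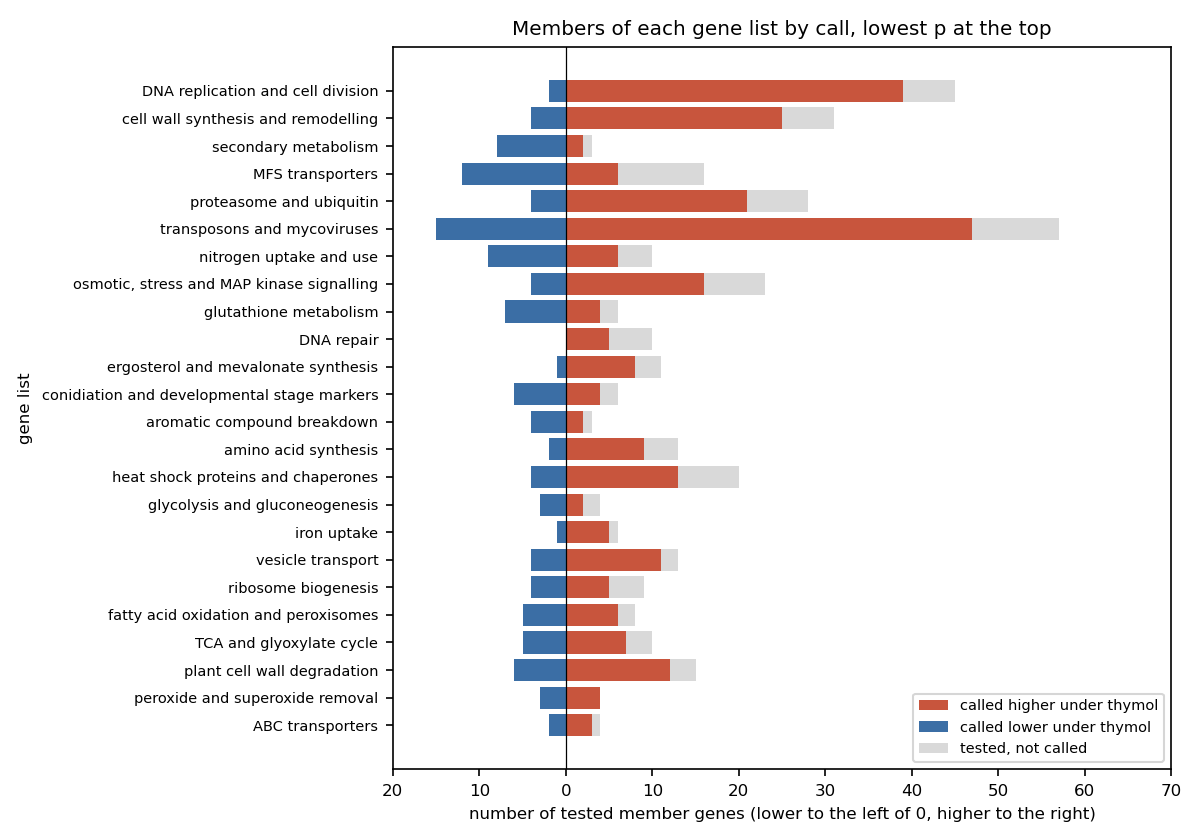
Bars count the tested members of each of 24 gene lists on the values as deposited, called higher under thymol (red, right of 0), called lower (blue, left of 0) or not called (grey), ordered by the p of Fisher's exact test. The top list, DNA replication and cell division, has 39 members higher and 2 lower. Relative to the median gene these counts move towards lower, except for ABC transporters, vesicle transport, secondary metabolism and aromatic compound breakdown, whose counts stay the same.

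No other list passed Fisher's exact test on the values as deposited or relative to the median gene. Of 72 tested members of the list of transposons and mycoviruses, 47 were higher and 15 lower (Fisher's exact test, adjusted p = 0.131). That list passed with median-ratio scaling (adjusted p = 0.0397), with upper-quartile scaling (0.0352) and with the directions of the authors' deposited table (7.66e-06), and had adjusted p = 0.675 with an estimated correlation. Nitrogen uptake and use had 6 members higher and 9 lower, glutathione metabolism 4 and 7, and stress and MAP kinase signalling 16 and 4 (adjusted p = 0.306 for each). DNA repair had 5 higher and 0 lower, and ergosterol and mevalonate synthesis, the route that azole fungicides block, 8 higher and 1 lower (adjusted p = 0.363 for each), with 7 higher and 4 lower in the ergosterol list relative to the median gene. Conidiation markers had 4 higher and 6 lower, aromatic compound breakdown 2 and 4, and amino acid synthesis 9 and 2. The lower conidiation markers included FOXG_04757 and FOXG_04758, through the word conidial in their best hit. Heat shock proteins and chaperones had 13 higher and 4 lower, glycolysis 2 and 3, iron uptake 5 and 1, and vesicle transport 11 and 4. Plant cell wall degradation had 12 higher and 6 lower. Ribosome biogenesis had 5 higher and 4 lower, fatty acid oxidation 6 and 5, and the TCA and glyoxylate cycle 7 and 5. These 3 lists turned to more members lower than higher relative to the median gene, at 2 and 5, 4 and 5, and 5 and 6. Peroxide and superoxide removal had 4 higher and 3 lower, and 3 and 3 relative to the median gene. The remaining 5 lists had under 5 tested members: cytochrome P450 (2 higher, 2 lower), the respiratory chain (1 and 2), ribosomal proteins (0 and 2), autophagy (0 and 1) and fatty acid synthesis (1 and 0). Matching by product name missed many P450 genes. Of 23 called annotated genes with the Pfam domain cytochrome P450, 18 were higher and 5 lower (Fisher's exact test, adjusted p = 0.288 over 52 domains). Relative to the median gene these counts were 15 and 5. Adjusted over the list alone, the stress signalling list had 23 calls against 20 over all genes tested. Other lists had equal counts or 1 more call adjusted over the list alone.

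The comparison with the authors' own calls asked how far both analyses point the same way. Conidiation-specific protein 10 (FOXG_01269) had a log2 fold change of 8.48 in the authors' deposited table, and 6.17 here on the values as deposited. Most of that gap comes from the pseudocount of 1, since the plain ratio of the mean FPKM values has a log2 of 8.08. For the exporter SNQ2 (FOXG_03541) the authors' deposited table gave 4.07, against 6.36 here and a log2 of 6.54 for the plain ratio. The authors' deposited table listed 4869 genes, 2381 higher and 2488 lower under thymol, each with an absolute log2 fold change of at least 1 and a false discovery rate of at most 0.00997. Of these, 3254 passed the expression filter here, 2512 were called by limma on the values as deposited, and 2490 (99.1%) of the called genes had the same direction. A further 2298 genes were called here and not listed by the authors, whose limits were stricter. With an absolute log2 change of at least 1 and an adjusted p under 0.01, limma called 2682 genes here. Of these, 1802 were in the authors' deposited table, 1790 of them with the same direction. Across the 3254 genes, which are not independent replicates, the fold changes had Pearson's r of 0.853 and Spearman's rho of 0.866, and those of the authors' deposited table lay lower by a median of 0.48 (authors' minus here, -0.48). The authors' deposited table gave group values of 30 or more to 530 of 953 cases in which a listed gene stood at 0 FPKM in every library of that group, and 238 of its genes stood at 0 FPKM in all 6 libraries.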

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

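The scalings other than median-ratio, upper-quartile and an equal FPKM sum, the fits without a trend or without genes at 0, and the list tests without reverse transcriptases or with the authors' direction were chosen after the data were seen. No paired analysis was possible because the labels give the groups no shared replicate numbers. The planned count models were not run on FPKM values, and the planned scalings and the test against a fold were applied to FPKM with limma. The total of 4810 calls stayed within 1.5 times except in the test against a fold of 1.5 (2554 calls, 1944 higher and 610 lower), and leaving out each library gave 4056 to 4816. Counts of higher calls fell by over 1.5 times with upper-quartile scaling (2255), quantile normalization (2103) and the median gene at 0 (1784). Counts of lower calls were 681 with at least 1 FPKM in all 6 libraries, and rose to 1716 with median-ratio scaling, 1903 with upper-quartile scaling, 1882 with quantile normalization and 2048 with the median gene at 0. The 28 named genes under 18 alternatives gave 494 values, 483 on the same side of the threshold, 6 that lost the call (all FOXG_00572), 5 that gained it, and 0 of the opposite direction. The number of gene lists past the threshold was 1, and stayed 1 without each library. It was 2 without a filter and with the median gene at 0, 3 with quantile normalization and when any annotation column could match, and 4 with median-ratio scaling, upper-quartile scaling, limma without a trend, without genes at 0 beside 10 FPKM or more, and with directions from the authors' deposited table. When any annotation column could match, the lists that passed included a list too small for the main test. Over 20 such alternatives the MFS list passed in 8, cell wall synthesis in 7 and transposons in 3, and secondary metabolism passed in 2 of the 19 in which it could be tested. The number was 0 in camera with an estimated correlation and 22 in fry. Fry gave the opposite direction to Fisher's exact test for peroxide removal (adjusted p = 5.09e-04), ABC transporters (adjusted p = 1.67e-04) and the TCA cycle (adjusted p = 0.0383). None of these lists passed Fisher's exact test. Fry asks about direction in itself and not relative to other genes. Fisher's exact test compared each list with a pool in which 62.3% of called genes were higher. A list with more members higher than lower could thus have negative log2 odds, here -0.37, -0.24 and -0.28 in the same order. Camera, which does compare with other genes, put the first 2 lists higher (adjusted p = 0.993 and 0.754) and the TCA cycle lower (0.893). At such p its directions carry no weight. The DNA replication list passed in every Fisher's exact test run, and lost its call only in camera with an estimated correlation. The authors' deposited calls with the same direction here numbered 2490, and 1338 with at least 1 FPKM in all 6 libraries, where fewer genes were tested. The absolute depth is unknown, so no floor can be set for genes listed at 0. The fit called 48.4% of simulated changes of log2 1, but only 200 of the 8478 simulated genes changed. With 4810 calls in the data the adjusted threshold admits larger p, so that share does not carry over.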

Other observations

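The genes, domains and locus-tag runs in this part were picked after their values were seen, and each gene named by level, except FOXG_05833, passed limma's threshold both as deposited and relative to the median gene. So were the tests of locus tags, of depth, of zeros by group, of the authors' values for genes listed at 0, and those of the hAT domain on the authors' directions.

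Subunits of the MCM helicase, which unwinds DNA in S phase, were higher under thymol together with the clamp that holds DNA polymerase. FOXG_10590 (mcm2) went from 2.69 ± 0.298 to 13.03 ± 0.328 FPKM (SD, n = 3 each), FOXG_04212 (mcm3) from 3.36 ± 0.216 to 15.3 ± 0.168, FOXG_00552 (mcm4) from 2.49 ± 0.597 to 14.6 ± 0.740, FOXG_02046 (mcm5) from 6.35 ± 0.278 to 19.3 ± 0.747, and FOXG_01697 (mcm7) from 4.62 ± 0.245 to 15.7 ± 0.928. FOXG_00337 (the clamp PCNA) went from 9.35 ± 3.71 to 40.6 ± 14.8 FPKM, and FOXG_00094 (a mitotic B-type cyclin) from 8.54 ± 1.15 to 30.2 ± 4.27. KOG classes of at least 10 called annotated genes were drawn from the same pool as the lists, so they are not independent evidence. Among them, replication, recombination and repair had 66 genes higher and 6 lower (Fisher's exact test, adjusted p = 3.62e-07 over 21 classes), and 45 and 6 relative to the median gene. Cytoskeleton had 26 higher and 2 lower (adjusted p = 0.00568). Inorganic ion transport had 13 higher and 24 lower (adjusted p = 0.00642), and 12 and 24 relative to the median gene. The other classes past 0.05 were cell cycle control (26 higher, 3 lower, adjusted p = 0.00847), energy production (19 and 25, adjusted p = 0.047) and protein turnover and chaperones (66 and 22, adjusted p = 0.047).

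Nitrate use, aromatic breakdown and glutathione conjugation held genes with large falls. FOXG_16837 (nitrate reductase) went from 12.8 ± 1.03 to 0.305 ± 0.023 FPKM (SD, n = 3 each). FOXG_17384 (phenol 2-monooxygenase, which hydroxylates phenols) went from 78.5 ± 8.67 to 2.56 ± 3.12 FPKM, and FOXG_03435 (homogentisate 1,2-dioxygenase) from 2803 ± 324 to 1017 ± 178. Both lists also held rises: FOXG_11029 (a dicarboxylic amino acid permease, nitrogen list) went from 0.406 ± 0.177 to 7.52 ± 5.04 FPKM. FOXG_08205 (best hit a 4,5-DOPA dioxygenase, aromatic list) went from 2.41 ± 0.462 to 11.9 ± 1.98. FOXG_04566 (glutathione S-transferase 1) went from 26.0 ± 3.55 to 2.20 ± 0.498 FPKM, while FOXG_07491 (glutathione S-transferase 3) went from 1.97 ± 0.938 to 22.6 ± 8.37. In sterol synthesis FOXG_06061 (squalene synthase) went from 9.94 ± 0.258 to 54.3 ± 10.5 FPKM and FOXG_10166 (sterol 24-C-methyltransferase) from 5.26 ± 0.853 to 35.3 ± 6.57. The most abundant member of that list, FOXG_05833 (HMG-CoA reductase), went the other way, from 53.2 ± 13.5 to 35.6 ± 7.01 FPKM, and was called lower relative to the median gene (log2 -1.16, limma adjusted p = 0.0105) but not as deposited (0.0936).

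All 6 tested genes numbered FOXG_04750 to FOXG_04758, which include the pigment polyketide synthase FOXG_04757, were lower, and the other 3 numbers are not in the deposited table. FOXG_04755 (an O-methyltransferase domain) went from 1432 ± 244 to 118 ± 31.2 FPKM, FOXG_04752 (an MFS carrier) from 265 ± 11.6 to 61.2 ± 22.03, and FOXG_04753 (a fungal transcription factor domain) from 51.6 ± 5.66 to 3.71 ± 1.12. A hypothesis is that genes lower under thymol lie side by side in groups. Of 391 genes lower by log2 1.5 or more, 38 pairs had consecutive locus tags, against a mean of 11.3 and a maximum of 25 in 10000 shuffles over the tested genes (1-sided permutation p = 0.0001, the smallest these shuffles can give). Relative to the median gene, 755 such genes gave 88 pairs against a mean of 42.2. Genes higher by as much relative to the median gene gave 40 pairs against 20.2 (1-sided permutation p = 0.0002), so adjacency was not limited to falls. Locus tags stand in for position, since no coordinates were used here.

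Depth does not account for the excess of higher over lower calls: a thymol library was deeper than a control library in 3 of 9 pairs, so the groups overlapped in sequencing depth. Rescaling by the FPKM sum without the 100 most abundant genes took the median shift from 0.60 to 0.289, between the bounds set beforehand for and against the composition of the libraries as its cause. Composition may thus hold part of the shift, and whether the rest is a wider rise of RNA per cell under thymol was not tested and stays open. The real split of the 6 libraries called 4810 genes and the highest of the other splits called 2. In 1 of 10 splits, the real one, as many genes were called, and 10 splits are too few for a share under 0.05.

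Genes listed at exactly 0 were the next pattern, with 102 genes at 0 in a single library beside others of the group at 10 FPKM or more. In the control group low depth does not account for most of them, since the library of lowest depth held 14 of 48 cases (29.2%, 95% Wilson interval 18.2% to 43.2%). In the thymol group replicates 1, 2 and 3 held 20, 26 and 8 of 54 cases: low depth stays open for replicate 2, the library of lowest depth (48.1%, 35.4% to 61.1%), but does not account for the other 28 cases, of which the deeper library, replicate 1, held 71.4% (52.9% to 84.7%). In 953 cases an annotated gene was listed at 0 in every library of a group, and the authors' deposited table gave 55.6% of these cases a value of 30 or more. These genes had all been called by the authors, which favours sizeable values. The share covers zeros of whole groups and was not measured for zeros in single libraries. A failed or reallocated estimate in the FPKM step is therefore a candidate explanation for zeros of whole groups, and was not tested for zeros in single libraries. No biological explanation was tested, and which zeros are real stays open.

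Of 40 tested genes with the dimerisation domain of hAT transposases, enzymes of DNA transposons, all 36 called were higher as deposited, with a median of 0.57 FPKM in control and 2.61 under thymol, and 18 of them were called higher relative to the median gene and 0 lower. Of 70 annotated genes of the domain, only these 40 were tested. With a control median below 1 FPKM, many of them could pass the filter only by being higher under thymol, which favoured higher calls. With at least 1 FPKM in all 6 libraries 8 genes of the domain were tested, and all 8 were called higher. Median-ratio, upper-quartile and quantile scaling, on the same 40 filtered genes, called 35, 35 and 31 higher and 0 lower. Tests of scaling and of low level set beforehand decided nothing and were replaced after they were seen: the share still called higher relative to the median gene lay between its bounds, and draws of called genes matched on control FPKM took the 36 genes as independent, in a domain picked for the lowest p of 52. The authors' deposited table, with 48.9% of its genes higher, had 98.6% of 70 such genes higher, so scaling does not account for the direction. Other genes of that table were higher in 51.3% when weighted to the same levels, and in 57.0% in the highest of 5 bins of level. That argues against low level in general only if the domain's genes are separate signals, since this comparison too takes them as independent. Reads shared between near-identical copies may make these genes 1 signal rather than many: the 36 genes carried 10 product names, which does not settle it, and without their sequences shared reads and separate rises under thymol cannot be told apart.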
